A study of Oncorhynchus mykiss with 12 samples.

How the data were processed

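Total RNA from the head kidney of juvenile rainbow trout (Oncorhynchus mykiss) was measured in 12 pools of 2 fish, 4 pools each from control fish, fish fed T3 and fish fed PTU. Per the labels, T3 was given at 20 µg per g of feed and PTU at 5000 µg per g of feed for 7 days. Per the labels' protocols, the RNA was copied into Cy3-labelled cDNA from an oligo(dT) primer, and each pool was hybridised in 1 colour. Per the file headers, the arrays were of a custom trout design and were read with Agilent Feature Extraction 10.7.3.1. Each array held 12884 spots for trout probes, each probe spotted once, and 536 manufacturer's control spots.

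The processed signal of each spot is a background-corrected brightness on a linear intensity scale, not scaled between arrays, per the file headers and the column names. The median signals of the spot and of its local background, also deposited by the authors as intensity, were used for an alternative background correction. The values in the deposited value table were a fraction: each equals the probe's processed signal divided by the sum over the trout probes of that array, with no log and no centring. This was found by setting each column against the processed signals of the same array, where the columns summed to between 0.99994 and 1.0001. The medians of the 12 columns ran from 2.9e-06 to 8.1e-06 of the array's signal. The formula is read from the values, since no source used here states how that table was made. 0 columns of other samples were in it.

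The choices in this paragraph were made before the data were examined. The processed signals were put on the log2 scale and each array's 75th percentile was subtracted. Control spots and spots marked as outliers by the scanner software were left out, and saturated spots (1 over all arrays) were kept. A probe was tested if it was well above background, by the scanner software's mark, on at least 3 of the 4 arrays of at least 1 group, which left 11762 probes. limma 3.58.1 in R 4.3.3 fitted the 3 groups together with a shared estimate of the spread per probe, and its moderated tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all tested probes of a comparison, with a threshold of 0.05. The comparisons were T3 against control, PTU against control and T3 against PTU.

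The fit was tested on simulated data with 200 of 11762 probes changed, in 10 rounds. The changes were spread evenly over 4 sizes. The noise was normal and independent between probes, without shifts shared by the probes of an array. For T3 against control it recovered 2.4% of 2-fold, 54.2% of 4-fold, 76% of 8-fold and 89.8% of 16-fold changes. For PTU against control it recovered 5%, 47.6%, 73.2% and 90% of changes of those sizes. False probes made up 5.2% of the calls for T3 and 6.09% for PTU. The real arrays do share such shifts, and the number of changed probes in them is unknown, so these shares need not hold there.

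The files do not pair the probe IDs with genes, and the trout gene table used for matching shared 0 IDs with the array. Gene lists fixed beforehand, from thyroid hormone signalling to cytokines and cell type markers, were therefore not analysed here. The rule for naming genes needed gene names as well. It was replaced, after the files were seen, by naming the 2 probes with the smallest p in each direction in T3 against control and in PTU against control.

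The control and T3 arrays lay on slide 1 and were read in scan 1. The PTU arrays lay on slide 2 and were read in scan 2. PTU and slide therefore cannot be told apart in any comparison with the other groups, and no block for slide could be fitted. T3 and control share a slide, so their comparison lies within it, although each group filled its own row of the slide. The labels name 6 aquaria of 10 fish but not which of them each pool came from. The pools are separate pairs of fish per the labels, and their number, 4 per group, limits the precision. With 12 pools and 6 aquaria, some pools must share an aquarium, and pools of a group can do so. Pools that share one are not independent replicates of a feed, so the p-values can be too small. The SE and p-values from limma therefore measure the spread between pools and not between aquaria, and an effect of aquarium could not be examined.

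Alternatives fixed beforehand were quantile normalization, median scaling, a percentile over probes well above background on all arrays, the deposited value table, other filters on dim probes, fits of only the groups compared, a replicate block, a variance trend with robust settings, array quality weights and the omission of each array in turn. 3 alternatives were chosen after seeing the data. They were normexp background correction with an offset of 50 on median signals, because the mean signal was not among the columns; a fit without the 3 arrays that stood apart; and a comparison of the PTU arrays with all 8 others.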

Results

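The study asked whether raised and lowered thyroid hormone status changes transcript levels in the trout head kidney, the blood-forming and lymphoid organ of bony fish. T3 (triiodothyronine) is the active thyroid hormone, and PTU (propylthiouracil) blocks thyroid hormone synthesis. The array carried selected immune-related trout genes, per the series design. Transcript levels were read on 12 arrays, 1 per pool of 2 fish, with 4 control, 4 T3 and 4 PTU pools. Levels are given as the log2 intensity minus the array's 75th percentile. Probes are named by their IDs, because the files do not pair the IDs with genes.

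Between 79.1% and 99.6% of the probes on an array were well above background, and 9872 probes were so on all 12 arrays. The median local background lay between 25 and 31 intensity units on all of them. On 3 arrays, 1 in each group, dim probes were raised against the other arrays. The dimmest 20% of the probes deviated from their medians over the 12 arrays by a median of 1.80 on the log2 scale in control replicate 2, 2.44 in T3 replicate 1 and 2.07 in PTU replicate 3. On the other 9 arrays this shift lay between -0.95 and 0.15. The 3 arrays also held the highest shares of probes well above background, 97.37% to 99.56% against 79.1% to 93.21% on the 9 others. Spots marked as outliers numbered 232 on T3 replicate 1, 61 on PTU replicate 3 and 16 on control replicate 2. The 9 others had 0 to 19. The median Spearman correlation of these 3 arrays with the rest, across probes, was 0.901, 0.852 and 0.897, against 0.932 to 0.952 for the 9 others. The first principal component, with 42.1% of the variance, placed the same 3 arrays at 88.4 to 128.7 and the others below 0. On the second component (14.5%) the control arrays lay between -43.95 and -11.8 and the PTU arrays between 6.13 and 59.97, while T3 replicate 4 lay at 34.3 and the other T3 arrays at 24.5, -49.9 and -32.4.

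**Figure D1:**
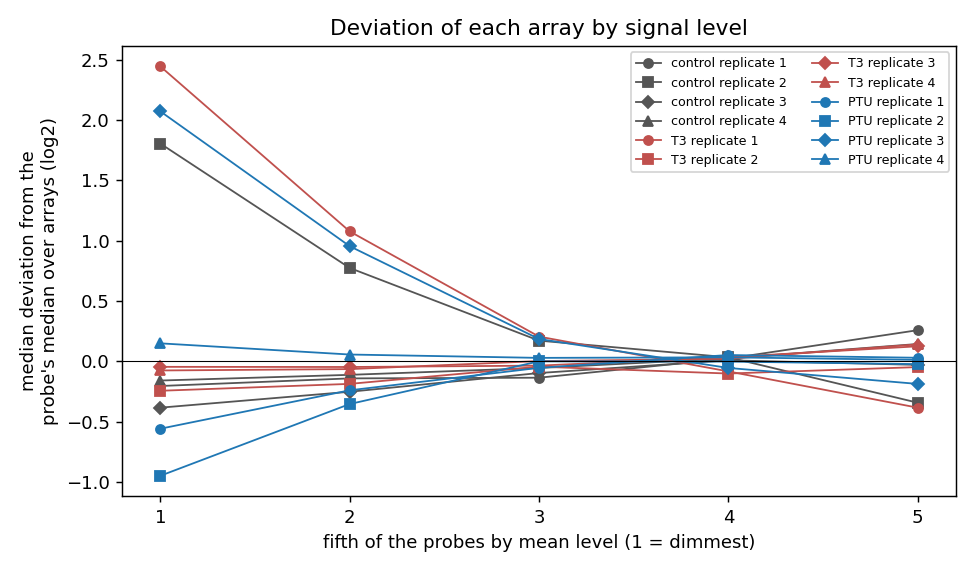
Median deviation of each array from the probes' medians over the 12 arrays (log2, vertical axis) for probes grouped by mean level (horizontal axis, dimmest at the left), 1 line per array coloured by group. Control replicate 2, T3 replicate 1 and PTU replicate 3 rise to between 1.80 and 2.44 in the dimmest group, and the other 9 arrays lie between -0.95 and 0.15 there.

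In fish fed T3, no probe passed the threshold against control. The probe JC006808 had the smallest p among those higher in T3, at -1.35 ± 0.479 (SD, n = 4) against -2.73 ± 0.363 in control (n = 4). Its log2 difference was 1.37 (SE 0.343, 95% interval 0.621 to 2.12) and its adjusted p from limma 0.855. After normexp correction of the median signals the log2 difference of JC006808 was 0.51, where the median over all probes was -0.34 (0.115 without that correction). JC001598, a bright probe, lay at 7.27 ± 1.04 in T3 and 5.49 ± 0.452 in control, a 3.45-fold difference with the same adjusted p. JC004530 lay lower in T3, at -1.74 ± 0.312 against -0.40 ± 0.598, and JC003477 at -1.41 ± 0.82 against 0.29 ± 0.533, each with an adjusted p of 0.855 from limma. All 4 T3 arrays lay beyond the control range for JC006808, JC001598 and JC004530, and 3 of 4 for JC003477. The PTU means lay on the same side of control: -1.71 ± 0.527 for JC006808, 6.34 ± 0.32 for JC001598, -1.43 ± 0.211 for JC004530 and -0.46 ± 0.391 for JC003477. Between T3 and PTU their adjusted p from limma was 0.704 to 0.964. The log2 differences, T3 minus PTU, were 0.35 for JC006808, 0.93 for JC001598, -0.31 for JC004530 and -0.95 for JC003477. Whether these probes differ in T3 alone is therefore left open. They were picked for a small p against control arrays that PTU shares, which favours PTU means on the same side.

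limma called 0 of the 11762 probes for T3 against control, with 637 (5.42%) at an unadjusted p under 0.05 where 588.1 would fall by chance. Of these, 244 were higher (38.3%, and between 8.51% and 51.2% under other scalings) and 393 lower in T3. With 1 array omitted the share higher ran from 29.3% (without control replicate 4) to 70.1% (without control replicate 2). It was 74.8% without the 3 arrays with raised dim probes, so the more frequent direction depends on single arrays. All alternatives also called 0 probes in this comparison. The count at an unadjusted p under 0.05 fell to 348 without control replicate 2, 285 without control replicate 3 and 382 without T3 replicate 4, and was 983 without control replicate 4 and 1033 with array quality weights. The median SE of a log2 difference was 0.435, and the 95% interval excluded a 2-fold difference in either direction for 26.3% of the probes.

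In fish fed PTU, no probe passed the threshold against control, and the 2 probes with the smallest p were lower than in control. JC007150 lay at -4.70 ± 0.925 (SD, n = 4) in PTU against -2.005 ± 0.097 in control (n = 4). Its log2 difference was -2.69 (SE 0.401, 95% interval -3.57 to -1.81), with an adjusted p from limma of 0.137. JC000708 lay at -4.54 ± 0.903 against -1.92 ± 0.19, a log2 difference of -2.62 with the same adjusted p. Both probes lay below the control range on all 4 PTU arrays. In T3 they lay at -2.04 ± 0.322 and -1.96 ± 0.347. Among probes higher in PTU, JC002877 lay at -3.14 ± 0.471 against -4.70 ± 0.255 in control, and JC006583 at -3.14 ± 0.897 against -6.17 ± 0.55, with adjusted p of 0.272 from limma for both. JC006583 was well above background on 3 of 4 control arrays, and its log2 difference was 3.03 (SE 0.579). In T3, JC002877 lay at -4.40 ± 0.307 and JC006583 at -4.65 ± 1.09. After normexp background correction of the median signals the log2 differences were -0.39 for JC002877 and -0.11 for JC006583, where the median over all probes was -0.51 (0.030 without that correction), so both lay below 0 but above the median probe.

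limma called 0 probes for PTU against control, with 1217 (10.3%) at an unadjusted p under 0.05, 600 higher (49.3%) and 617 lower. The share higher was between 30.8% and 61.6% under other scalings and 7.65% after normexp background correction. Quantile normalization called 7 probes, array quality weights 5, omission of PTU replicate 3 called 4 and omission of the 3 arrays with raised dim probes 3, all of them lower in PTU; the remaining alternatives called 0. JC007150 and JC000708 were each past the threshold in 4 of 24 alternatives, with adjusted p for JC007150 between 0.00178 and 0.58. Without PTU replicate 2 the count at an unadjusted p under 0.05 was 811, and after normexp correction it was 3139. All PTU arrays lay on slide 2 and all control arrays on slide 1, so treatment and slide cannot be told apart here.

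**Figure D2:**
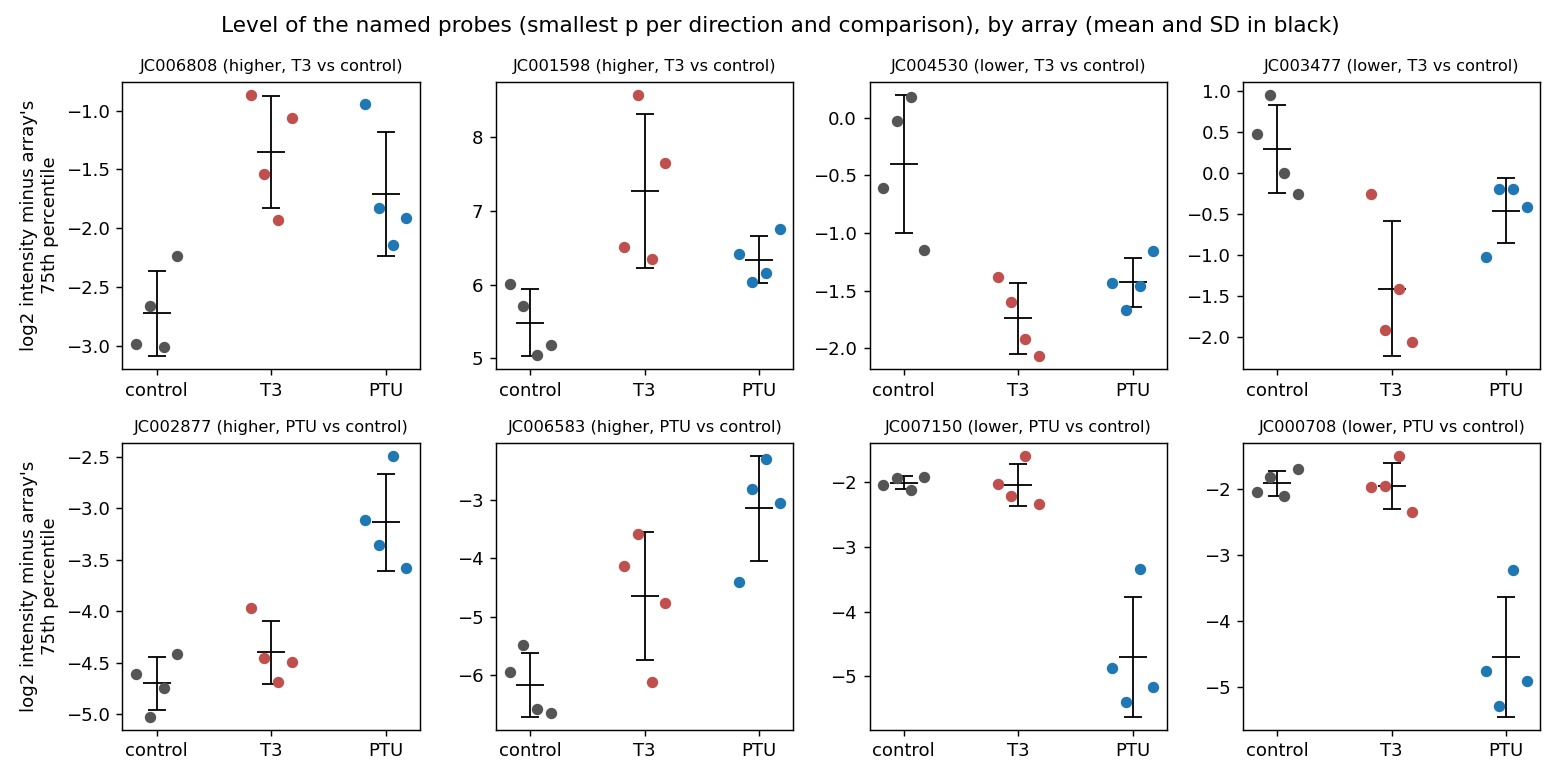
Level of each named probe on each array (points, log2 intensity minus the array's 75th percentile) in the control, T3 and PTU groups, with the mean and SD of the 4 arrays of a group in black. JC007150 and JC000708 lie near -2 in control and T3, and their PTU means are -4.70 and -4.54.

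Between T3 and PTU directly, JC007150 was 2.66 and JC000708 2.59 higher on the log2 scale in T3, each with an adjusted p of 0.114 from limma. limma called 0 probes, with 810 (6.89%) at an unadjusted p under 0.05, of which 479 were higher in T3 (59.1%). The share higher was between 36.9% and 57.7% under other scalings and 74% after normexp background correction. Quantile normalization called 4 probes, array quality weights 10, omission of PTU replicate 3 called 3 and omission of the 3 arrays with raised dim probes 2, all higher in T3; the remaining alternatives called 0. Without PTU replicate 2 the count at an unadjusted p under 0.05 was 459, and without PTU replicate 3 it was 1348. Slide and treatment coincide in this comparison as well.

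Across the tested probes, which are not independent replicates, the differences of T3 and of PTU from control correlated with a Pearson r of 0.484 and a Spearman rho of 0.475. Pearson r was 0.301 without T3 replicate 4. Both comparisons use the same control arrays, and 100 simulations of unchanged groups with shared controls gave a mean r of 0.5 and rho of 0.462. The simulated noise was independent between probes and left out the shifts that probes of a real array share. Near values therefore do not show that shared controls alone account for the correlation. The covariance was 0.192 against 0.202 in the simulations, a difference of -0.0105. With different control arrays for each treatment, the mean r over 6 ways of dividing the controls was 0.0146, between -0.0791 and 0.169.

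**Figure D3:**
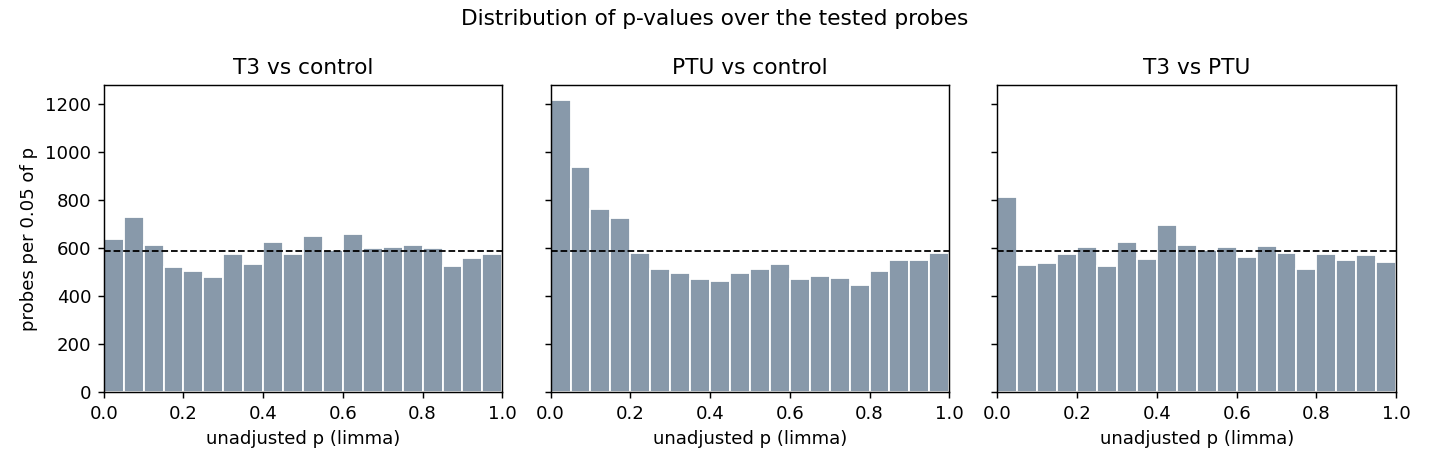
Number of tested probes (vertical axis) by unadjusted p from limma (horizontal axis, bars of width 0.05) in the 3 comparisons, with the 588.1 probes per bar that chance gives as a dashed line. The leftmost bar holds 637 probes for T3 against control, 1217 for PTU against control and 810 for T3 against PTU.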

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

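The tests of the 3 arrays with raised dim probes were chosen after the result was seen, as was the rule by which control probes were examined. That rule replaced a stricter one, all 4 arrays of a treated group above every control array, which 0 of 57 control probes met. An array was singled out when its gap to the nearest other array of its group was large against the group's range; of 54 groups of 4 values examined, 7 met this, and chance alone gives about 1 in 20.

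Control replicate 2 and T3 replicate 1 stood apart in the shift of their dimmest probes (1.80 and 2.44 on the log2 scale) and in their median Spearman correlation with the other arrays (0.901 and 0.852). Control replicate 2 also did so in the width of its signal distribution, with 7.05 log2 units between its 10th and 90th percentiles against 9.14 to 9.33 in the other controls. T3 replicate 4 had a median local background of 26 intensity units against 27 on the other T3 arrays.

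The raised dim probes on control replicate 2, T3 replicate 1 and PTU replicate 3 were weighed against 3 explanations, and no treatment separates these arrays, since 1 lies in each group. A change in trout transcripts alone is argued against by the manufacturer's E1A control probes: the dimmest of them, set against the 5 brightest on the same array, was the highest of its group on all 3 arrays, which chance gives with probability 0.0156. This log2 contrast was -5.20 on control replicate 2 (at most -9.90 on the other controls) and -5.09 on T3 replicate 1 (at most -8.59 on the other T3 arrays). On PTU replicate 3 it was -8.34 against -8.97 on PTU replicate 4, a small gap, so the argument is weak for that array. A regional defect is argued against as well, since position on the array explained at most 0.497% of the deviation on these arrays and up to 1.16% on the other 9. A higher background of the glass or scan is argued against on control replicate 2. There the negative control spots rose by 0.0683 of the rise of the dim probes (0.0429 to 0.0883 against each other control array), under the 0.1 set as excluding it. Such a background stays open in part on T3 replicate 1 (0.0665, from 0.0273 to 0.102) and PTU replicate 3 (0.115, from 0.0869 to 0.132), all below the 0.5 set as the cause. A background that arises in hybridisation is not covered by this test, and other steps of labelling or hybridisation were not tested.

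The control probe ETG10_195139, 1 of 57 control probes examined, had a PTU mean above every control array. It lay at -0.29 ± 1.66 (SD, n = 4) in PTU, -2.74 ± 1.5 in T3 and -3.31 ± 1.51 in control, a difference of 3.02 on the log2 scale between PTU and control. Within the controls, replicate 4 stood apart at -1.045 against -4.09 to -4.04 in the others. Replicate 4 was also the highest array of the T3 group, at -0.53 against -3.76 to -3.07, and of the PTU group, at 1.69. 1 of the 4 T3 arrays and 2 of the 4 PTU arrays lay above all control arrays.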

How the results depend on the processing

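Normexp (on median signals), the omission of the 3 arrays together and the settings tried for the correlation other than quantile normalization, no filter and omitting 1 array were chosen after the result was seen. The count of 0 for T3 against control held in all settings run. For PTU against control, quantile normalization called 7 probes, array quality weights 5 and omission of the 3 arrays 3; for T3 against PTU these called 4, 10 and 2. Omitting 1 array gave 0 to 4 and 0 to 3 calls, the highest without PTU replicate 3. Quantile normalization and array weights shared 4 probes for PTU against control. The cause was not tested, beyond a median SE of 0.365 without the 3 arrays against 0.435.

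The correlation of both effects was 0.708 after normexp and 0.301 (without T3 replicate 4) to 0.592 (without control replicate 4) with 1 array omitted. Normexp moved the median difference of all probes to -0.34 for T3 and -0.51 for PTU, from 0.115 and 0.030. With it JC002877 lay at -0.39 and JC006583 at -0.11, below 0 but above that median. Of 191 values of the named probes 189 kept their sign, but for many of them this was fixed in advance. Another filter or variance setting, or omission of an array of the third group, leaves a log2 difference unchanged. Median scaling moved that of T3 to -0.107, and the deposited table that of T3 against PTU to -0.148 from 0.011. Normexp gave 3139 probes at an unadjusted p under 0.05 for PTU, of which 7.65% were higher. For T3 against PTU that count was 531 after normexp, 1556 with array weights and 1570 without the 3 arrays (810 as reported). Across scalings the share higher ran from 8.51% to 51.2% for T3 (38.3% as reported), 30.8% to 61.6% for PTU (49.3%) and 36.9% to 57.7% for T3 against PTU (59.1%). After normexp it was 10.8%, 7.65% and 74%. For T3 it ran from 29.3% (without control replicate 4) to 70.1% (without control replicate 2) with 1 array omitted. It was 74.8% without the 3 arrays, so the more frequent direction for T3 depends on single arrays.

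With the replicate number as a block, limma called 0 probes in each comparison, with 555, 1100 and 661 at an unadjusted p under 0.05. The labels tie the numbers to nothing shared, and deviations of same-numbered arrays correlated between -0.369 and 0.351, over 0.1 in 3 of 12 pairs; an array's best match in another group had its number in 4 of 24 cases. Gene lists and 1 row per gene were not run without gene names, nor a slide block for PTU. The number of arrays limits precision. Normexp changed the signal column and the background step and added an offset of 50, which weighs most on dim probes. The effects of these 3 changes were not told apart.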

Other observations

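The comparison of the PTU arrays with all others, the test of slide against treatment, the correlations of called probes and the count over divisions that part the arrays with raised dim probes were chosen after the result was seen.

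With the 4 PTU arrays set against the 8 control and T3 arrays, limma called 5 probes, all lower on the PTU arrays, between 4.12-fold and 6.38-fold, with 1120 at an unadjusted p under 0.05. 4 of the 5 shared the smallest adjusted p (0.0143 from limma). JC007150 and JC000708, with the smallest unadjusted p, had log2 differences of -2.67 and -2.60, and JC007150 lay below all 8 other arrays on all 4 PTU arrays. The 5 calls need not be separate transcripts. Over the 8 other arrays JC007150 and JC000708 correlated with a Pearson r of 0.929 (exact permutation p 0.00176, adjusted 0.0176 over 10 pairs) and a Spearman rho of 0.857 (exact permutation p 0.0107, adjusted 0.107). Without the 2 arrays farthest from the median r was 0.723. JC009103 and JC002661 had an r of 0.923 (exact permutation p 0.0146, adjusted 0.073), and 0.872 without the 2 arrays farthest from the median. In the remaining pairs r lay between -0.206 and 0.503, with adjusted permutation p of 0.592 or above. The number called was 0 without PTU replicate 1, 2 or 4, and 116 without PTU replicate 3, of which 4 were higher on the PTU arrays. It was 140 without the 3 arrays with raised dim probes, 19 of them higher, and 274 with array quality weights, 66 of them higher. Quantile normalization called 11 and the other scalings 4 to 6, all lower. The count at an unadjusted p under 0.05 was 663 without PTU replicate 2, 1961 without the 3 arrays and 2034 with array quality weights.

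Of 100 divisions into 4 and 8 arrays, drawn from 495 and the real one included, 3 called at least 5 probes, but the comparison was itself picked from these data, so this share does not exclude chance. The highest other, 2616 probes, put all 3 arrays with raised dim probes among the 4. These arrays were singled out for a shift they share, so a high count follows from that choice and tells nothing of its cause. Of the 53 drawn divisions with 1 of these arrays among the 4, as in the real one, 1 called at least 5 probes, the real one itself. That share has the same limit. Neighbouring spots had a median log2 difference of -0.0801 and probes of like level one of 0.0395, which argues against a local defect or a shift of that signal level on slide 2. An effect of PTU may account for the 5 probes, and so may slide or scan: 0 arrays separate slide from treatment, so these cannot be told apart.

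Over all divisions, chance cannot be excluded for the counts at an unadjusted p under 0.05 in fits of only the groups compared. For T3 against control, 18 of 35 divisions of the 8 arrays gave at least the real 523, and the highest other gave 1515. For PTU against control 8 of 35 gave at least 1050 (highest other 1871), and for T3 against PTU 10 of 35 gave at least 774 (highest other 2773). In each comparison the highest other division put both arrays with raised dim probes on one side. A high count there follows from the shift for which these arrays were singled out and tells nothing of its cause. The real division is among the 20 that part these arrays, where the smallest share possible is 0.05, too large to fall under the bound. The highest other of these gave 746 for T3 against control (real 523), 846 for PTU against control (real 1050) and 461 for T3 against PTU (real 774).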
